A study of Homo sapiens with 34 samples.

How the data were processed

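The series followed human embryonic stem cells through cardiac differentiation and asked what SETD7, a SET-domain lysine methyltransferase, binds and does on the way. The established H7 line was kept on Matrigel in E8 medium and taken to beating cardiomyocytes as a monolayer with small molecules, per the labels' protocols. Total RNA was sequenced at days 0, 2, 5 and 9 with 2 samples per day, and SETD7 chromatin immunoprecipitation (ChIP) was sequenced on the same days with 2 samples per day. Acetylation of histone H3 lysine 27 (H3K27ac) and input DNA were sequenced with 1 sample per day. In the HES3 line, another established embryonic stem cell line, SETD7 wild-type and knockout cells at the mesoderm stage were profiled for RNA polymerase II (Pol2) and for its serine 2 phosphorylated form (S2P), with 2 samples per genotype and antibody, and for trimethylation of histone H3 lysine 36 (H3K36me3), with 1 sample per genotype. The labels used here list 34 samples, of which 8 are RNA-seq and 26 are ChIP or input. Nothing in the labels says that samples with the same group name came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

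Sample groups, gene lists, tests, thresholds and most alternatives were set before the data were examined, and alternatives added later are named as such. Column names in the RNA table gave the stages embryonic stem cell, mesoderm, cardiac progenitor and cardiomyocyte, which the sample labels tie to days 0, 2, 5 and 9. Input libraries were not used in any test here.

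The submitters' processing notes name STAR, Bowtie, featureCounts, DESeq and the genome build hg19, with no versions or settings. The RNA and SETD7 ChIP tables hold variance-stabilized values that the authors deposited on a log2-like scale. For high values this scale runs close to log2 of reads over a library size factor, and it compresses the changes of low genes. The lowest value in the RNA table, 0.46 after rounding, was the value of a gene with no reads. Which part of each gene was counted in the SETD7 and H3K27ac tables, and whether input was subtracted, is not given in the sources used here. The H3K27ac table holds the authors' log2 fold changes over day 0 per gene, from 1 library per day.

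For Pol2 and S2P the deposited tables came from diffReps 1.55.4, per the file headers. They list regions from a G-test on reads with a window of 1000 bp, a step of 100 bp, a fragment size of 100 bp, a p cutoff of 0.0001 and a deviation cutoff of 20. Mutant libraries were the treatment and wild type the control, so a log2 fold change above 0 was higher in the mutant. Per the file headers, region counts (a coverage signal) were divided by normalization constants of 0.80 and 1.05 for the Pol2 mutant libraries and 1.21 for the control. The S2P constants were 0.75 and 1.24 for the mutant libraries and 1.06 for the control. One constant was listed for the control although the labels list 2 wild-type libraries, so the spread between wild-type libraries is not seen in these tables. The deposited p-values and adjusted p-values are the authors' own, and a test on reads of this kind compares those libraries, not the genotypes. H3K36me3 peaks were called with HOMER 4.6 in its histone mode against input, separately per library, per the file headers. That caller required a fold over input of 4 and a tag count of 21 in the knockout and 16 in the wild-type library. The peak score and the fold ratio over input in those deposited files are the authors' values per peak and were used only within a list. Tag counts were normalized per library, per the file headers, and the fragment lengths were 164 bp in the knockout and 116 bp in the wild-type library.

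Read depth was recovered from the stabilized tables, in which a size factor per sample and a shared curve turn whole counts into values. All values of the 16 columns (100%) came out within 0.1 of a whole read. RNA libraries held 23804352 and 28188914 reads at day 0, 35280881 and 30636612 at day 2, 36544967 and 36836595 at day 5, and 39302385 and 39814274 at day 9, replicate 1 first. The SETD7 ChIP libraries held 11981244 and 6574072 reads at day 0, 11711647 and 5160872 at day 2, 10384981 and 8007882 at day 5, and 14437671 and 5180332 at day 9. H3K36me3 libraries held 38554266 tags in the knockout and 24393345 in the wild type. Intervals and read floors cover counting error only. No pair of replicates agreed within sampling noise: the mean chi-square per gene with at least 10 reads was at least 4.71, so none was counted as a duplicate.

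Differences between consecutive days were tested with limma 3.58.1 (lmFit, then eBayes with a trend on the mean level) in R 4.3.3 on the stabilized values. All 8 samples of a table entered a single fit with day as the only factor. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes kept. A gene was called higher or lower at an adjusted p under 0.05 and an absolute difference of at least 1. Genes were kept where their mean over the samples lay more than 1 above the table minimum, which left 27130 of 55870 RNA entries and 19317 of 20245 SETD7 entries. SE is the moderated standard error of a difference, SD the spread of the 2 samples of a day. Where a gene had no reads on a day, its fold was given as a lower bound against a floor of 3 reads per library, and list medians were also taken with such genes at their bound.

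Whether replicate numbers pair the samples across days was checked from the correlation of replicate differences between days. In the SETD7 ChIP table all 6 correlations lay between 0.63 and 0.78, so the numbers pair those samples, and replicate 1 was also the deeper library on every day. Values with the replicate number as a block stand beside the SETD7 results they change.

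Gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over 18 lists and 3 steps together, and again with a correlation estimated from the data. The lists covered pluripotency, primitive streak and early mesoderm, cardiac progenitors, sarcomere and contraction, cardiac ion handling and hormones, endoderm, neural ectoderm, endothelium and blood, and smooth muscle with fibroblast and epicardium. They also covered WNT targets and inhibitors, cell cycle, oxidative phosphorylation with fatty acid oxidation, glycolysis, H3K36 and H3K4 methylation enzymes, RNA polymerase II pausing and elongation, mitochondrially encoded genes, ribosomal proteins and stress response. Mitochondrially encoded genes and ribosomal proteins were listed as markers of RNA quality. Members of each list were counted as called over all genes and also as adjusted over the list alone.

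Genes named in the text were chosen by rule: SETD7, the 5 largest rises and 5 largest falls among called protein-coding genes per RNA step, the 2 to 4 largest called members of each list at the step with most calls, and members that go against the list's title. For SETD7 ChIP the rule took the 3 smallest p-values per step without a call and the 3 largest changes in either direction with the block. The 5 smallest p-values per direction were taken for Pol2 and S2P, with ties ranked by fold change, the 5 highest and 5 lowest list genes at day 2 for H3K27ac, and the 5 best-scored peaks per library for H3K36me3. Other list members named as examples were chosen after their values were seen. Y-linked genes were left out of the named genes. A few further list members are not reported here. Regions and peaks at genes of the lists, which the rule also asked for, were not looked up.

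Because H3K27ac had 1 library per day, each list median was placed among 10000 random lists of the same size matched on mean RNA level in 20 bins. SETD7 and RNA changes were compared across genes by Spearman correlation, which gets no p-value because genes are not replicates. Regions and peaks were compared by an overlap of at least 1 bp, in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The overlap of S2P with Pol2 regions was set against 100 shifts of the S2P regions along the genome. Coordinates are hg19 positions as the files give them, counted from 1. No hg19 gene annotation was used here, so regions and peaks are given by position and not by gene, and the SETD7 locus itself was not examined in the knockout libraries. Gene lengths came from a GRCh38 gene table, used for names and lengths only.

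Day 0 to day 2 counts were simulated at 1 dispersion per table, without the wider day 0 RNA spread, so real rates may differ. In 28589 RNA genes the fit recovered 25.4% of 2-fold, 77.6% of 4-fold and 89.4% of 8-fold changes (7 false calls). In 19404 SETD7 entries these were 43.3%, 97% and 98.5% (1 false call). Alternatives covered the replicate block, other filters and scalings, stricter thresholds, no eBayes trend and only the compared days. Each sample was left out in turn, and limma's voom on recovered reads was added later.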

Results

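Gene expression was measured by RNA-seq in H7 embryonic stem cells at days 0, 2, 5 and 9 of cardiac differentiation, with 2 samples per day and 23804352 to 39814274 reads per sample. SETD7 ChIP-seq signal was measured on the same days, with 2 samples per day and 5160872 to 14437671 reads per sample. H3K27ac, a mark of active promoters and enhancers, was given for 1 library per day as change from day 0. In HES3 cells at the mesoderm stage, Pol2 and S2P were compared between SETD7 mutant and wild-type cells, and H3K36me3, a mark of transcribed gene bodies, was given as 1 peak list per genotype. Values for RNA and SETD7 ChIP are on the deposited variance-stabilized scale, on which a difference of 1 is about 2-fold for well-read genes and understates the change of low ones.

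SETD7 RNA stood at 9.02 ± 0.34 at day 0, 9.65 ± 0.18 at day 2, 10.26 ± 0.03 at day 5 and 11.51 ± 0.06 at day 9 (SD, n = 2 per day). The rise of 1.25 from day 5 to day 9 passed the test (SE 0.22, adjusted p = 0.0081). The differences of 0.63 to day 2 (SE 0.22, adjusted p = 0.09) and 0.60 to day 5 (SE 0.22, adjusted p = 0.12) did not. The call at day 9 was lost when either day 5 or either day 9 sample was left out, with differences of 1.27 and 1.23 without day 5 replicates 1 and 2, and 1.21 and 1.30 without day 9 replicates 1 and 2.

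The step from day 0 to day 2 covered the entry of pluripotent cells into mesoderm. EOMES, a T-box regulator of mesendoderm, went from 1.07 ± 0.86 to 14.20 ± 0.03 (SD, n = 2), a difference of 13.14 (SE 0.39, adjusted p = 3.4e-06). The secreted WNT inhibitors DKK4 and DKK1 rose by 13.96 (SE 0.81, adjusted p = 4.8e-05) and 11.14 (SE 0.24, adjusted p = 5.4e-07), and T, the mesoderm factor brachyury, rose by 10.13 (SE 0.56, adjusted p = 4.5e-05). These genes had almost no reads at day 0, so their changes are given on the stabilized scale alone. LHX1, a LIM-homeobox gene of the streak, had no reads at day 0 and was at least 829-fold higher at day 2 (adjusted p = 9.4e-07). The growth factor FGF17 was at least 761-fold higher and SP5, a WNT-responsive transcription factor, at least 521-fold higher (adjusted p = 4.9e-05 and 6.8e-06). Among falls, the imprinted gene PEG3 was at least 211-fold lower (adjusted p = 7.4e-05), the homeobox gene HMX2 at least 32.6-fold lower and the sodium channel gene SCN1A at least 35.5-fold lower. ATP10B, a lipid flippase gene, fell by 6.71 (SE 0.64, adjusted p = 0.00055) and KLHDC7A by 6.66 (SE 0.78, adjusted p = 0.0013).

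Primitive streak and early mesoderm genes rose as a group, with 19 of 24 measured members higher and 0 lower, and 19 higher adjusted over the list alone. Their median difference was 5.62, or 4.47 with genes without reads at their bound (camera adjusted p = 1.4e-19, and 0.019 with an estimated correlation). WNT targets and inhibitors followed, with 12 of 21 higher and 1 lower, 13 and 2 adjusted over the list alone, a median of 2.43, or 1.75 at the bounds, and a camera adjusted p of 7.1e-08 (adjusted p = 0.021 with an estimated correlation). Among these the ligand WNT3 rose by 4.34, the WNT effector LEF1 by 4.20 and the ligand WNT5A by 3.15, while MYC, a proliferation gene, fell by 3.85. Cardiac progenitor genes had 11 of 24 higher and 1 lower, 12 and 2 adjusted over the list alone, with GATA6, a cardiac and endodermal regulator, up by 9.36 (SE 1.08, adjusted p = 0.0013), GATA4 up by 7.78 and MYOCD, a coactivator of muscle genes, down by 2.75 (SE 0.65, adjusted p = 0.024). Their median was 1.87, or 1.54 at the bounds, and the camera call (adjusted p = 0.00081) was lost with adjusted p = 0.45 with an estimated correlation and at 0.053 without day 0 replicate 1. In day 0 replicate 2 progenitor genes lay a median of 1.53 above replicate 1. Pluripotency genes had 7 of 19 lower and 1 higher, 8 and 2 adjusted over the list alone. The median was -1.31 (camera adjusted p = 0.0017, adjusted p = 0.15 with an estimated correlation). ZFP42, a marker of naive-type pluripotency, fell by 3.03 and TERF1, a telomere protein gene, fell by 2.64. The core factors POU5F1, NANOG and SOX2 differed by -1.31, -1.82 and -0.04 and were not called (adjusted p = 0.14, 0.13 and 0.97).

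Markers of other lineages moved in both directions. Endoderm genes had 7 of 21 higher and 2 lower, 7 and 3 adjusted over the list alone, with a median of 0.06, or 0.04 at the bounds, and a mean of 1.80 (camera adjusted p = 0.014, adjusted p = 0.17 with an estimated correlation). SOX17 and FOXA2, regulators of definitive endoderm, rose by 9.80 and 8.10, and the plasma protein genes AFP and APOB fell by 3.12 and 2.00. Neural ectoderm genes had 6 of 17 higher and 3 lower, the same counts adjusted over the list alone, and a median of 0.49 that was not called (camera adjusted p = 0.13). SIX3, a forebrain factor, was at least 622-fold higher (adjusted p = 3.8e-06), ZIC1 rose by 6.05 and PAX7 by 4.79, while SOX3 fell by 5.15, DCX by 1.66 and NES by 1.04. Endothelium and blood genes had 3 of 21 higher, which were the globin HBE1 and the blood regulators RUNX1 and GATA2, and 5 lower, among them the endothelial genes TEK and ERG at -4.91 and -4.48. That list had 4 and 8 adjusted over the list alone and a median of -0.43, not called (camera adjusted p = 0.13, and 0.020, lower, without day 0 replicate 1). Smooth muscle, fibroblast and epicardium genes had 2 of 26 higher, the matrix enzyme LOX at 2.83 and the retinoic acid enzyme ALDH1A2 at 2.09, and 7 lower, with 3 and 8 adjusted over the list alone. Their median was -1.21, or -0.84 at the bounds (camera adjusted p = 0.064, and 0.00016, lower, without day 0 replicate 1), and in day 0 replicate 2 they lay a median of 1.27 above replicate 1.

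Sarcomere genes, which make the contractile apparatus, had 5 of 28 lower and 2 higher, 8 and 2 adjusted over the list alone. Their median was -0.88. TNNC1, ACTC1, TNNT2, MYL7 and TPM1 fell by 3.70, 3.01, 2.63, 2.56 and 1.72, and MYH6 rose by 2.46. This camera call (adjusted p = 0.0071) was lost with adjusted p = 0.54 with an estimated correlation and at 0.56 without day 0 replicate 2, in which sarcomere genes lay a median of 1.89 above replicate 1. Ion handling and hormone genes had 4 of 22 lower, among them NPPB, KCNE1 and CACNA1D, and the potassium channel gene KCNJ2 higher, 5 and 1 adjusted over the list alone. The median was -0.56, or -0.38 at the bounds (camera adjusted p = 0.19). Cell cycle genes had 4 of 30 lower (BUB1B, CCNB2, PCNA and TPX2) and 0 higher, 5 and 0 adjusted over the list alone. The median was -0.78 (camera adjusted p = 8.3e-07, and 0.048 with an estimated correlation). Oxidative phosphorylation and fatty acid oxidation had 7 of 31 lower and 2 higher (ESRRG and CPT1A), 7 and 4 adjusted over the list alone. Their median was -0.64 (camera adjusted p = 0.0050, adjusted p = 0.17 with an estimated correlation).

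Glycolysis had PDK1 and BNIP3 higher and the glucose transporter SLC2A1 and PGAM1 lower of 21, also adjusted over the list alone. The median was -0.41 (camera adjusted p = 0.13, and 3.7e-05, lower, without day 0 replicate 2). Among H3K36 and H3K4 methylation enzymes SMYD2 rose by 2.66, KDM1A fell by 1.26 and SMYD5 by 1.05 of 34 measured, also adjusted over the list alone. The median was -0.12 (camera adjusted p = 0.27, and 0.022, lower, without day 0 replicate 1). Of 33 genes of Pol2 pausing and elongation, 4 rose and 0 fell, also adjusted over the list alone. They were LARP7 and HEXIM1, parts of the complex that holds back the elongation kinase, at 2.31 (SE 0.18, adjusted p = 2e-04) and 1.35 (SE 0.31, adjusted p = 0.022), and the elongation factors ELL2 and AFF1 at 1.94 and 1.42. That list had a median of 0.05 and a mean of 0.09 while its test pointed down (camera adjusted p = 0.94). Mitochondrially encoded genes had MT-ATP8 and MT-ND3 higher of 13, also adjusted over the list alone. Their median was 0.80 (camera adjusted p = 0.016, adjusted p = 0.61 with an estimated correlation, and 0.85 without day 0 replicate 1). Ribosomal protein genes had RPL7 at -1.38 and RPS4X at -1.25 lower of 28, 1 adjusted over the list alone. The median was -0.40 (camera adjusted p = 0.054). That test pointed up without day 0 replicate 1 (adjusted p = 0.00057) and down without replicate 2 (adjusted p = 5.2e-14), and centring gave a lower call (adjusted p = 0.039). Stress response genes had 3 of 22 higher (HSPA1A, JUN and GADD45A) and 5 lower, 3 and 6 adjusted over the list alone. The median was -0.29 (camera adjusted p = 0.17, and 0.0096, lower, without day 0 replicate 2). CHAC1, TRIB3 and ASNS, targets of the amino acid response, fell by 2.86, 2.79 and 2.59. Day 0 replicate 2 lay a median of 1.85 above replicate 1 at mitochondrially encoded genes and 1.93, 1.04 and 1.32 below it at ribosomal protein, glycolysis and stress genes (medians of -1.93, -1.04 and -1.32).

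In all, 2148 genes were called higher and 1809 lower at day 2 of 27130 tested, against 8654 at an unadjusted p under 0.05, where chance gives 1356. Centring on sample medians gave 1577 and 3066, mostly lower. A fit on days 0 and 2 alone, without later days to dilute the day 0 spread, gave 41 and 4. The higher and lower counts were 3733 higher without day 0 replicate 1, 3804 and 3456 without day 0 replicate 2, 657 and 537 without day 2 replicate 1, 606 and 481 without day 2 replicate 2, 1376 and 1176 without day 5 replicate 1, and 1366 and 1174 without day 5 replicate 2. Leaving out either day 2 sample ended the calls of PAX7 (4.85 and 4.73), AFF1 (1.49 and 1.35), HSPA1A (2.24 and 2.29), HEXIM1 (1.37 and 1.33), CHAC1 (-3.01 and -2.72), RPL7 (-1.56 and -1.19) and RPS4X (-1.30 and -1.20), and leaving out replicate 1 that of SOX3 (-4.66). HEXIM1 and RPL7 were also lost without day 0 replicate 2 (0.86 and -0.91) and, like CHAC1, without any 1 sample of day 5 or 9, at differences of 1.35, -1.38 and -2.86, and RPS4X without day 0 replicate 1 (-0.88).

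Between day 2 and day 5 the labels go from mesoderm to cardiac progenitors. HAND1, a cardiac and lateral mesoderm factor, had no reads at day 2 and stood at 10.46 ± 0.15 at day 5 (SD, n = 2), at least 431-fold higher (adjusted p = 2.1e-05). CBLN2, a synaptic organizer gene, and HNF4A, a hepatocyte nuclear factor, were at least 478-fold and 357-fold higher (adjusted p = 4.2e-05 and 1.2e-05). SYTL5, a vesicle trafficking gene, rose by 9.91 (SE 0.54, adjusted p = 4.2e-05) and the fibrillar collagen gene COL3A1 by 9.82 (SE 2.33, adjusted p = 0.026). MIXL1, a streak homeobox gene, fell by 9.33 from 15.37 ± 0.12 to 6.04 ± 0.80 (SE 0.35, adjusted p = 1.2e-05). CER1, a secreted NODAL and BMP inhibitor, fell by 10.58 (SE 0.70, adjusted p = 7.1e-05), DKK4 by 10.53, FGF17 by 9.98, and the surface protein gene CD48 was at least 356-fold lower.

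Pluripotency genes fell, with 17 of 19 lower and 0 higher, 17 lower adjusted over the list alone. Their median was -3.51 (camera adjusted p = 6.2e-16, and 0.019 with an estimated correlation). POU5F1 fell by 6.08 (SE 0.54, adjusted p = 0.00024), SOX2 by 6.68 (SE 0.38, adjusted p = 4.7e-05), NANOG by 6.28 and the noncoding gene ESRG by 7.43. Streak genes had 15 of 24 lower and 1 higher, 16 and 1 adjusted over the list alone. The median was -2.71 (camera adjusted p = 3.4e-10, and 0.019 with an estimated correlation), and the exception was KDR, a receptor of vascular progenitors, at 2.86. Cardiac progenitor genes had 17 of 24 higher and 1 lower (IRX3 at -1.21), 18 and 2 adjusted over the list alone. The median was 3.90 (camera adjusted p = 1.5e-12, adjusted p = 0.17 with an estimated correlation). Beside HAND1, the ligand BMP5 rose by 9.07, MYOCD by 9.01 (SE 0.65, adjusted p = 9.5e-05) and MEF2C by 8.00. Sarcomere genes had 14 of 28 higher and 0 lower, 17 and 0 adjusted over the list alone. Their median was 2.92 (camera adjusted p = 2.7e-12, adjusted p = 0.17 with an estimated correlation), with the atrial myosin gene MYH6 up by 8.10, cardiac actin ACTC1 by 7.27 and TNNT2 by 6.55. Ion handling and hormone genes had 8 of 22 higher and 2 lower (KCNJ2 at -5.27 and TRDN at -3.66), 11 and 3 adjusted over the list alone. The median was 1.51 (camera adjusted p = 0.010, adjusted p = 0.18 with an estimated correlation). The natriuretic peptide gene NPPB in this list rose by 7.81.

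Endothelium and blood genes had 16 of 21 higher and 0 lower, 17 and 0 adjusted over the list alone. The median was 3.10, or 2.88 at the bounds (camera adjusted p = 3.6e-15, adjusted p = 0.061 with an estimated correlation). The endothelial cadherin gene CDH5 was at least 189-fold higher, and CD34, FLI1 and TAL1, genes of vascular and blood progenitors, rose by 8.09, 7.12 and 6.52. Smooth muscle, fibroblast and epicardium genes had 15 of 26 higher and 1 lower (LOX at -3.96), the same adjusted over the list alone. Their median was 2.83 (camera adjusted p = 2.1e-09, adjusted p = 0.15 with an estimated correlation), with LUM at 7.76, ACTA2 at 6.74 and the epicardial gene BNC1 at 5.54. Endoderm genes had 13 of 21 higher and 1 lower (SOX17 at -1.51), 15 and 1 adjusted over the list alone. The median was 2.20 (camera adjusted p = 4.5e-11, and 0.019 with an estimated correlation). In that list the plasma transport gene TTR rose from no reads, and GATA3 and APOB rose by 9.05 and 8.89. Neural ectoderm genes had 7 of 17 lower and 2 higher (LHX2 at 3.77 and NES at 1.57), 10 and 4 adjusted over the list alone. The median was -1.52 (camera adjusted p = 0.015, adjusted p = 0.16 with an estimated correlation, and 0.051 without day 0 replicate 1).

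WNT targets and inhibitors split, with 6 of 21 higher and 9 lower, 7 and 9 adjusted over the list alone. Their median was -0.55 (camera adjusted p = 0.25). DKK1 fell by 5.81 (SE 0.24, adjusted p = 2e-05), whereas the inhibitor SFRP5 rose by 6.04 and BAMBI by 3.49. Glycolysis had 6 of 21 lower and 0 higher, 8 lower adjusted over the list alone. The median was -0.75 (camera adjusted p = 0.00084, adjusted p = 0.45 with an estimated correlation), with BNIP3, LDHA and PGK1 at -2.92, -2.46 and -2.08. Mitochondrially encoded genes had 6 of 13 lower, 12 adjusted over the list alone. The median was -1.80 (camera adjusted p = 2e-06, adjusted p = 0.41 with an estimated correlation), with MT-ATP8, MT-ND6, MT-ATP6 and MT-ND3 down by 2.98, 2.15, 2.03 and 1.82. Cell cycle had CENPE at -2.31 and BUB1 at -1.70 lower of 30, also adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.22). Oxidative phosphorylation and fatty acid oxidation had 4 of 31 higher (MB, CKM, PPARGC1A and FABP3) and 2 lower (CPT1A and ESRRG), also adjusted over the list alone. The median was 0.05 (camera adjusted p = 0.97). Methylation enzymes had the muscle methyltransferase SMYD1 at 7.65 and ASH2L at 1.22 higher of 34, also adjusted over the list alone. The median was 0.11 (camera adjusted p = 0.41). Pausing and elongation genes had LARP7, ELL2, AFF1 and CDK7 lower of 33 at -2.37, -2.06, -1.26 and -1.25, also adjusted over the list alone, with a median of 0.01, a mean of -0.16 and a test pointing down (camera adjusted p = 0.33). Ribosomal protein genes had 0 of 28 called, also adjusted over the list alone. Their median was 0.11 (camera adjusted p = 0.81), and stress genes had ASNS alone lower of 22 at -1.36, also adjusted over the list alone. The median was 0.02 (camera adjusted p = 0.92).

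At day 5, 1834 genes were called higher and 1686 lower, against 7344 at an unadjusted p under 0.05. The higher and lower counts were 2910 higher without day 0 replicate 1, 2913 higher without day 0 replicate 2, 941 and 671 without day 2 replicate 1, 894 and 653 without day 2 replicate 2, 767 and 681 without day 5 replicate 1, and 761 and 726 without day 5 replicate 2. Leaving out any 1 sample of day 2 or 5 ended the calls of COL3A1 (8.59 to 11.06), ACTA2 (6.63 to 6.85), MT-ATP8 (-3.16 to -2.80), MT-ND6 (-2.21 to -2.09), MT-ATP6 (-2.06 to -1.99) and MT-ND3 (-1.91 to -1.73), and COL3A1, MT-ND6 and MT-ATP6 were also lost without either day 9 sample at 9.82, -2.15 and -2.03.

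From day 5 to day 9 the labels go from cardiac progenitors to cardiomyocytes. MYH7, the slow cardiac myosin heavy chain, went from 5.91 ± 0.26 to 14.47 ± 0.19 (SD, n = 2), a rise of 8.56 (SE 0.54, adjusted p = 0.00016). MYPN, a Z-disc gene, had no reads at day 5 and was at least 232-fold higher (adjusted p = 0.00024). GJA3, a connexin gene, rose by 10.03 (SE 0.69, adjusted p = 2e-04), the Z-disc gene MYOZ2 by 8.85 (SE 1.02, adjusted p = 0.0014) and the laminin gene LAMA4 by 8.42 (SE 0.70, adjusted p = 0.00035). The largest falls were in SCN7A, a sodium channel gene, by 6.06 (SE 0.58), TRPM6, a magnesium channel gene, by 5.99 (SE 0.61), MOBP by 5.77, STEAP1B by 5.58 and FOXI2 by 5.56, with adjusted p of 0.0074 or lower.

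Sarcomere genes had 22 of 28 higher and 0 lower, 26 and 0 adjusted over the list alone. The median was 4.43 (camera adjusted p = 1.6e-19, adjusted p = 0.13 with an estimated correlation). The ventricular light chain gene MYL3 rose by 8.01 (SE 0.99, adjusted p = 0.0017) and MYBPC3, a myosin-binding protein gene, by 7.21 (SE 1.07, adjusted p = 0.0038). Ion handling and hormone genes had 18 of 22 higher and 1 lower (the connexin gene GJA1 at -2.32), 20 and 1 adjusted over the list alone. Their median was 3.21 (camera adjusted p = 5.6e-14, and 0.019 with an estimated correlation). NPPA, the atrial natriuretic peptide gene, went from 5.89 ± 0.55 to 14.03 ± 0.10, a rise of 8.14 (SE 1.30, adjusted p = 0.0053). The calcium pump regulators SLN and PLN rose by 5.86 and 4.39, the calcium release channel RYR2 by 4.50, HRC by 4.72 and the calcium channel gene CACNA1C by 4.63. Cardiac progenitor genes had 6 of 24 higher and 1 lower (BMP4 at -1.91), 8 and 1 adjusted over the list alone. The median was 1.23 (camera adjusted p = 0.00047, adjusted p = 0.45 with an estimated correlation), with IRX4, HCN4 and NKX2-5 up by 6.40, 3.89 and 2.87.

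Oxidative phosphorylation and fatty acid oxidation had 18 of 31 higher and 0 lower, the same adjusted over the list alone. The median was 1.33 (camera adjusted p = 3.6e-15, and 0.019 with an estimated correlation). The creatine kinase gene CKM rose by 6.77, the fatty acid carrier FABP3 by 4.86, the ADP/ATP carrier SLC25A4 by 4.06 (SE 0.17, adjusted p = 8.4e-05), and the heart isoform gene COX6A2 was at least 30.7-fold higher. Glycolysis had 16 of 21 higher and 0 lower, 18 and 0 adjusted over the list alone. Their median was 2.37 (camera adjusted p = 3e-14, adjusted p = 0.15 with an estimated correlation), with ALDOC at 4.15, LDHA at 3.39, ALDOA at 3.22 and BNIP3 at 3.05. Cell cycle genes had 11 of 30 lower and 0 higher, 14 lower adjusted over the list alone. The median was -1.11 (camera adjusted p = 1.9e-12, and 0.019 with an estimated correlation), with the replication genes CDC6, RRM2, MCM2 and MCM4 down by 2.30, 1.94, 1.89 and 1.80. Pluripotency genes had 13 of 19 lower and 0 higher, 14 lower adjusted over the list alone. The median was -2.21, or -1.82 at the bounds (camera adjusted p = 1.4e-13, and 0.019 with an estimated correlation). Streak genes had 7 of 24 lower and 2 higher (WNT8A at 2.32 and MIXL1 at 2.21), 7 and 3 adjusted over the list alone. Their median was -0.75, with EOMES down by 4.79. That call (camera adjusted p = 0.042) was lost with adjusted p = 0.17 with an estimated correlation and at 0.068, 0.070, 0.12 and 0.067 without day 2 replicates 1 and 2, day 5 replicate 1 and day 9 replicate 1.

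Smooth muscle, fibroblast and epicardium genes had 9 of 26 higher and 1 lower (BNC1 at -1.69), 11 and 2 adjusted over the list alone. The median was 1.21 (camera adjusted p = 0.00066, adjusted p = 0.34 with an estimated correlation), with the proteoglycan gene DCN at 5.48, LOX at 4.59 and the epicardial factor WT1 at 4.35. Endoderm genes had 5 of 21 higher, the plasma protein genes AFP, SERPINA1, TF, FGB and FGA at 8.21, 7.15, 3.76, 3.43 and 2.45, and 6 lower, among them GATA3 at -3.51 and SOX17 at -3.08. That list had 6 and 8 adjusted over the list alone, a median of -0.62, a mean of 0.44 and a test pointing down (camera adjusted p = 0.73). Endothelium and blood had EMCN at 6.03 and ENG at 3.39 higher and VWF at -4.58, CD34 at -2.14 and KDR at -1.36 lower of 21, also adjusted over the list alone. The median was -0.18 (camera adjusted p = 0.45). Neural ectoderm had NES higher and OTX2, SIX3, FABP7 and ZIC2 lower of 17, also adjusted over the list alone. Their median was -0.71 (camera adjusted p = 0.19). WNT targets and inhibitors had WNT11, WNT5B, DKK1 and MYC higher and SP5, LGR5 and NKD1 lower of 21, 5 and 4 adjusted over the list alone, with a median of 0.16, a mean of -0.15 and a test pointing up (camera adjusted p = 0.83).

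Among methylation enzymes SMYD2, KDM4B, SETD7 and KDM4C rose by 1.76, 1.63, 1.25 and 1.10 and SETMAR fell by 1.16 of 34, also adjusted over the list alone, with a median of -0.23, a mean of 0.02 and a test pointing down (camera adjusted p = 0.41). Pausing and elongation genes had LARP7 at -1.35 and SUPT16H at -1.28 lower of 33, also adjusted over the list alone. The median was -0.11 (camera adjusted p = 0.40). Stress genes had CDKN1A, DDIT4 and DUSP1 higher of 22 at 4.09, 3.20 and 1.25, 4 adjusted over the list alone. The median was 0.50 (camera adjusted p = 0.0094, adjusted p = 0.55 with an estimated correlation). Mitochondrially encoded genes had 0 of 13 called, also adjusted over the list alone. Their median was 0.84 (camera adjusted p = 0.0036, adjusted p = 0.55 with an estimated correlation, and 0.10 without day 9 replicate 2). Ribosomal protein genes had RPS6 alone lower of 28 at -1.16, also adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.19, and 0.0053 and 0.0048, lower, without day 0 replicates 1 and 2).

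At day 9, 1878 genes were called higher and 1500 lower, against 7648 at an unadjusted p under 0.05. The higher and lower counts were 2910 and 2627 without day 0 replicate 1, 2911 and 2622 without day 0 replicate 2, 991 lower without day 2 replicate 1, 986 lower without day 2 replicate 2, 614 and 338 without day 5 replicate 1, 623 and 332 without day 5 replicate 2, 611 and 508 without day 9 replicate 1, and 605 and 478 without day 9 replicate 2. Leaving out any 1 sample of day 5 or 9 ended the calls of NPPA (7.75 to 8.53), MYBPC3 (7.08 to 7.34), SMYD2 (1.71 to 1.82), KDM4B (1.56 to 1.71), SETMAR (-1.20 to -1.11) and ALDOA (2.98 to 3.45), the last 3 also without either day 2 sample at 1.63, -1.16 and 3.22. FOXI2 was lost without day 5 replicate 1 or 2 or day 9 replicate 1 (-5.60, -5.51 and -4.21), MCM2 without day 5 replicate 1 or 2 or day 9 replicate 2 (-1.73, -2.05 and -1.62), ALDOC without day 5 replicate 2 or day 9 replicate 1 (4.11 and 4.03) and SLN without day 5 replicate 1 (5.39).

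**Figure D1:**
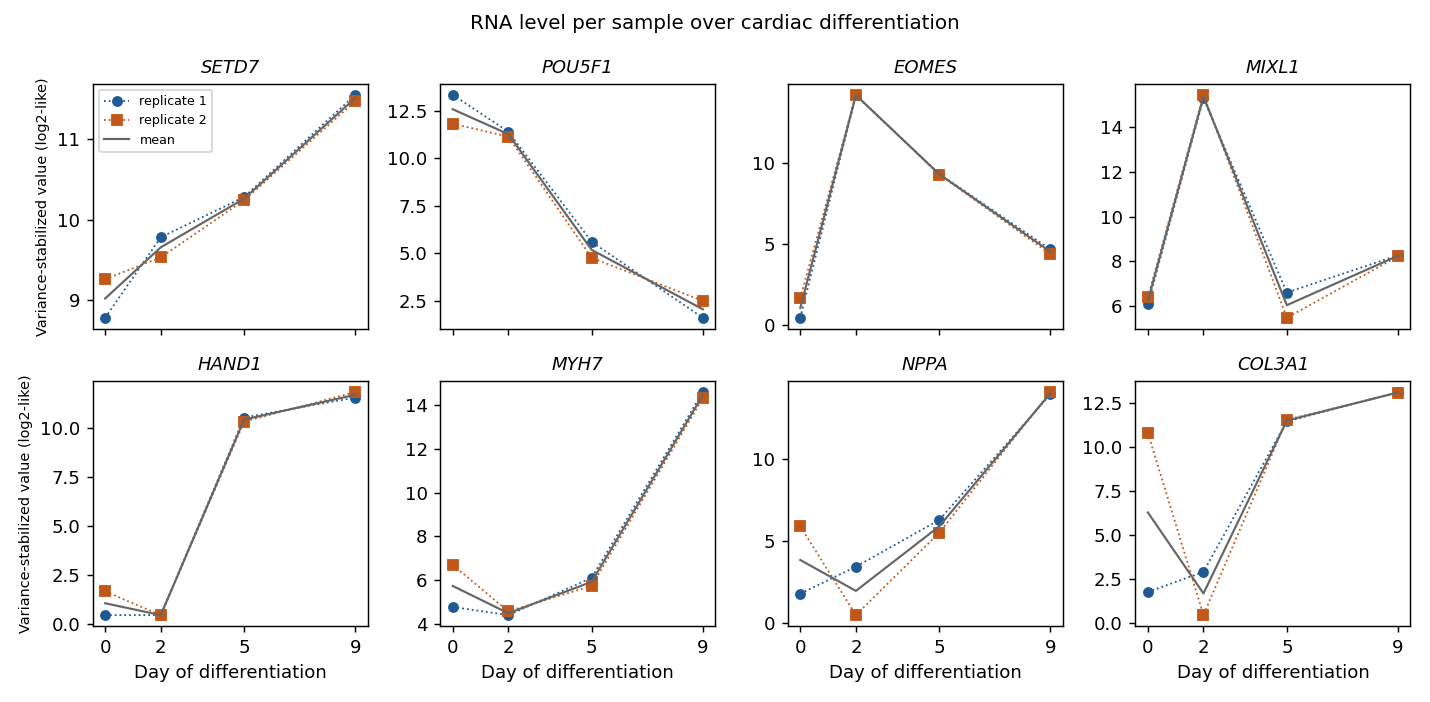
RNA level on the variance-stabilized scale (y axis, log2-like) against day of differentiation (x axis) for 8 genes, with circles for replicate 1, squares for replicate 2 and a grey line for the mean of 2 samples. EOMES stood at 1.07 at day 0 and 14.20 at day 2, MYH7 at 5.91 at day 5 and 14.47 at day 9, and COL3A1 at 1.77 and 10.82 in day 0 replicates 1 and 2.

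SETD7 ChIP asked where the enzyme is bound. Between day 0 and day 2 the fit with the replicate number as a block called some genes of the streak and of WNT signalling. DKK1 went from 4.95 ± 0.15 to 8.80 ± 2.15 (SD, n = 2), a rise of 3.85 (SE 0.58, adjusted p = 0.016 with the block), T rose by 3.64 (SE 0.51, adjusted p = 0.014) and SP5 by 3.15 (SE 0.56, adjusted p = 0.036). MIXL1 rose by 2.93, APLNR, the apelin receptor gene of early mesoderm, by 2.90, GATA6 by 2.70, the WNT feedback inhibitors NKD1 and AXIN2 by 2.48 and 1.58, WNT5A by 2.01 and LEF1 by 1.66, all at an adjusted p of 0.041 or lower with the block. Signal fell at TPM1, a tropomyosin gene, by 2.15 (SE 0.34, adjusted p = 0.023), at CYR61 by 2.11 (SE 0.37, adjusted p = 0.035) and at JADE1 by 2.07 (SE 0.30, adjusted p = 0.015). Falls also covered the pluripotent surface protein gene PODXL at -2.0, AASS at -1.96, the Polycomb cofactor gene JARID2 at -1.88, TERF1 at -1.59, the deubiquitinase gene USP9X at -1.57 (SE 0.14, adjusted p = 0.0021) and the growth factor gene FGF2 at -1.33.

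From day 2 to day 5, again with the block, signal rose at TPM1 by 2.51 (SE 0.34, adjusted p = 0.020), at the Notch ligand gene JAG1 by 2.36 (SE 0.23, adjusted p = 0.0045), at RP11-216L13.17 and CCDC183 by 2.13 each, at PDGFRA, a receptor of cardiac mesoderm, by 2.04 (SE 0.27, adjusted p = 0.020), and at the homeobox genes MEIS1 and PBX3 by 1.94 and 1.16. MIXL1 fell by 3.17 (SE 0.37, adjusted p = 0.015) and AXIN2 by 1.54 (SE 0.20, adjusted p = 0.019), and LAMA1 differed by 0.96, under the size asked for. From day 5 to day 9 no gene was called with the block, and the smallest p-values were at MT-ND3 (1.22, adjusted p = 0.14 with the block), LAMA1 (-0.85, adjusted p = 0.15) and MT-CO1 (1.07, adjusted p = 0.25). At the SETD7 gene itself the ChIP signal was 8.62 ± 0.42, 9.13 ± 0.15, 9.17 ± 0.04 and 9.0 ± 0.22 on the 4 days (SD, n = 2), with no call at any step in either fit.

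Without the block limma called 0 genes higher and 0 lower at every step, with 338, 252 and 58 genes at an unadjusted p under 0.05 where chance gives 966, and voom also called 0. With the block it called 28 higher and 40 lower at day 2, 7 and 2 at day 5, and 0 and 0 at day 9, with 1949, 1298 and 595 genes at an unadjusted p under 0.05, and voom with the block called 33 and 54, 11 and 6, and 0 and 0. Without day 2 replicate 1 the fit without block called 4 genes higher at day 2, NKD1 at 3.21, DKK1 at 5.37, T at 4.93 and SP5 at 4.77, and 2 lower at day 5, and without day 9 replicate 1 it called 1 higher at day 9.

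**Figure D2:**
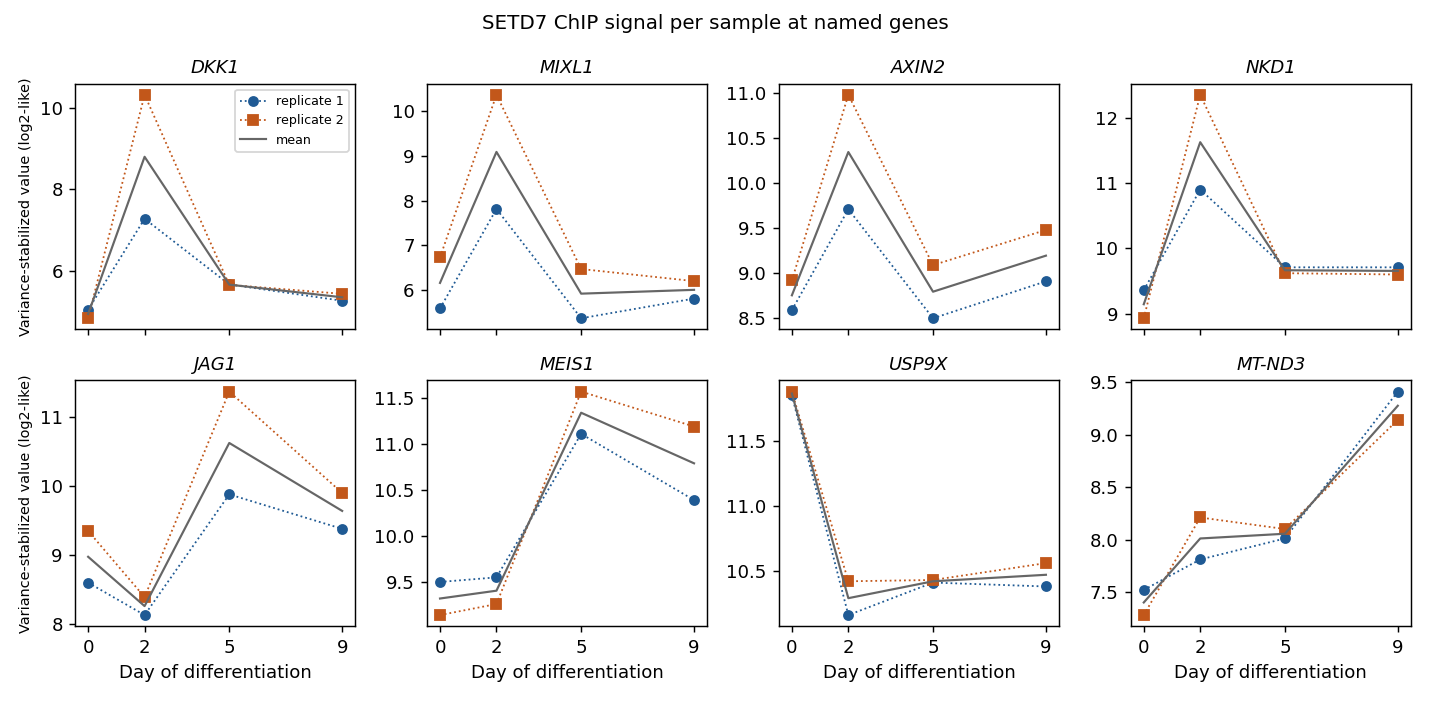
SETD7 ChIP signal on the variance-stabilized scale (y axis, log2-like) against day (x axis) at 8 genes, with circles for replicate 1, squares for replicate 2 and a grey line for the mean of 2 samples. DKK1 stood at 5.05 and 4.84 at day 0 and at 7.28 and 10.32 at day 2, and USP9X at 11.85 and 11.88 at day 0 and at 10.16 and 10.42 at day 2.

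By list, SETD7 signal at streak genes was higher at day 2 at a median of 1.31, with 0 of 26 called over all genes, 13 higher adjusted over the list alone and 5 with the block (camera adjusted p = 2.9e-36, adjusted p = 0.32 with an estimated correlation and 0.43 with the block as well). WNT genes had a median of 0.42 with 7 of 22 higher adjusted over the list alone and 6 with the block (camera adjusted p = 4.6e-11, and 0.32 with an estimated correlation and 0.43 with the block as well). Pluripotency genes lay at -0.81 with 1 of 19 lower adjusted over the list alone (camera adjusted p = 9.8e-14, and 0.32). Estimating the correlation (0.041 to 0.97 in called lists, preset 0.01) ended every SETD7 list call (adjusted p at least 0.32). It also raises p-values at estimates under 0.01, as in RNA. The remaining lists are given by median and preset-correlation adjusted p. At day 2 these were mitochondrially encoded genes at 0.79 (2.9e-14), glycolysis at -0.37 (3.2e-05), ribosomal protein genes at -0.40 (0.00099), cardiac progenitor genes at 0.22 (0.00026), endothelium and blood at 0.17 (0.028), cell cycle at -0.13 (0.048), methylation enzymes at -0.13 (0.048), and pausing and elongation at -0.11 (0.040). Lists without a call at day 2 were sarcomere at 0.17, ion handling at 0.08, endoderm at 0.20, neural ectoderm at 0.06, fibroblast and epicardium at 0.03, oxidative phosphorylation at -0.08 and stress at -0.21, the last called lower with the block (adjusted p = 0.0088). Without day 0 replicate 2 or day 2 replicate 1 the direction at day 2 turned to higher for cell cycle (adjusted p = 0.0092 and 0.0024) and ribosomal protein genes (0.0086 and 0.0089). The calls of glycolysis (0.44 and 0.44), endothelium (0.90 and 0.40), methylation enzymes (0.47 and 0.86) and pausing and elongation (0.16 and 0.61) ended without either of the same libraries. Without day 0 replicate 1 and without day 2 replicate 2 stress genes were called lower at day 2 (0.0070 and 0.0012). Endoderm, at 0.053 with all samples, was called higher without day 0 replicate 1 (0.038), day 5 replicate 2 (0.048), day 9 replicate 1 (0.043) or day 9 replicate 2 (0.049). The call of progenitor genes ended without day 0 replicate 2 (0.36), and that of methylation enzymes also without day 5 replicate 1 (0.060). Centring ended the calls of methylation enzymes (0.056) and of pausing and elongation (0.052). The omissions here and at the later steps were fitted without the block, so the difference between replicates 1 and 2 entered the step.

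At day 5 SETD7 signal was lower at streak genes, with a median of -1.20 (camera adjusted p = 1.3e-23) and 7 of 26 lower and 1 higher adjusted over the list alone, and at WNT genes at -0.35 (7e-06) with 5 of 22 lower adjusted over the list alone. It was higher at cardiac progenitor genes at 0.91 (9.2e-19), sarcomere genes at 0.72 (8.3e-15), ion handling genes at 0.27 (2.6e-06), fibroblast and epicardium genes at 0.13 (0.00062) and mitochondrially encoded genes at 0.31 (0.00045), and lower at pluripotency genes at -0.48 (4.4e-08), cell cycle at -0.27 (7e-06) and ribosomal protein genes at -0.41 (6e-04). Endoderm at 0.08, neural ectoderm at 0.09, endothelium at 0.05, oxidative phosphorylation at 0.13, glycolysis at -0.16, methylation enzymes at -0.02, pausing and elongation at -0.08 and stress at -0.05 were not called, and endoderm and endothelium had means of -0.02 and methylation enzymes of 0.03, opposite to their medians. Glycolysis was called lower with the block (adjusted p = 0.038), without day 2 replicate 1 (0.011) and without day 5 replicate 2 (0.0069), and higher without day 2 replicate 2 (0.038). Without day 2 replicate 2 ribosomal protein genes also turned to higher (adjusted p = 0.00066) and the call of cell cycle ended (0.13). Calls also ended for fibroblast and epicardium genes without day 5 replicate 2 (0.067), and for mitochondrially encoded and ribosomal protein genes without day 5 replicate 1 (0.44 and 0.98). Other lists gained a call at day 5. Without day 2 replicate 1 and without day 5 replicate 2 these were pausing and elongation (0.0070 and 0.030) and stress (0.0053 and 0.00039), each lower. Oxidative phosphorylation was higher without day 2 replicate 2 (0.015) and without day 5 replicate 1 (0.0032), and methylation enzymes were higher without day 2 replicate 2 (0.048).

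At day 9 SETD7 signal was higher at mitochondrially encoded genes at 1.07 (3.8e-40, 5 of 13 adjusted over the list alone), sarcomere genes at 0.47 (6.7e-10), glycolysis at 0.39 (2.5e-07), cardiac progenitor genes at 0.23 (0.00036), ion handling at 0.18 (6e-04) and oxidative phosphorylation at 0.16 (0.00045), and lower at cell cycle genes at -0.29 (5.5e-10). Without a call at day 9 were pluripotency and streak genes at -0.09 each, endoderm at -0.03, neural ectoderm at -0.10, fibroblast and epicardium at -0.11, WNT genes at 0.03, methylation enzymes at 0.02, ribosomal protein genes at -0.16 and stress genes at 0.08. Endothelium lay at -0.01 with a mean of 0.01 and a test pointing up, and pausing and elongation at 0.01 with a mean of -0.01 and a test pointing down. With the block ribosomal protein genes were called lower (adjusted p = 0.024). Without day 5 replicate 1 progenitor genes turned to lower (adjusted p = 0.0080), and without day 9 replicate 2 their call ended (0.13). Without those libraries in turn the calls also ended for sarcomere (0.79 and 0.59), ion handling (0.47 and 0.29), oxidative phosphorylation (0.86 and 0.33) and glycolysis (0.16 and 0.89), while those of mitochondrially encoded and cell cycle genes stayed. Methylation enzymes were called higher without day 9 replicate 1 (0.035) and lower without day 9 replicate 2 (0.028). Other lists also gained a call at day 9. Ribosomal protein genes were lower without day 5 replicate 1 (7.2e-05) and without day 9 replicate 2 (7.8e-08), and streak genes were lower without day 2 replicate 1 (0.045), day 2 replicate 2 (0.043) or day 5 replicate 1 (0.049). Stress genes were higher without day 5 replicate 2 (0.0013) and without day 9 replicate 1 (0.035), and WNT genes higher without day 5 replicate 2 (0.034). Fibroblast and epicardium genes were lower without day 5 replicate 1 (0.010) and endoderm without day 9 replicate 1 (0.022). Without day 9 replicate 2 endothelium was higher (0.0094) and pausing and elongation lower (0.0095).

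Among genes with the largest SETD7 rises, more were called higher than lower in RNA. The 500 genes with the largest SETD7 rises had median RNA differences of 1.26, 1.60 and 1.38 at days 2, 5 and 9, above all 10000 random lists matched on RNA level at each step, and 211, 252 and 223 of them were called higher in RNA and 18, 13 and 8 lower. The 500 largest falls had medians of -0.70, -0.49 and -0.53, below all random lists, and 146, 157 and 91 of them were called lower in RNA and 12, 10 and 15 higher. Among genes called with the block at day 2, 19 of 25 with higher SETD7 signal were higher in RNA at a median of 3.26, and 23 of 38 with lower signal were lower at a median of -1.39. Across 15964 genes the Spearman correlation of SETD7 and RNA differences was 0.23, 0.25 and 0.29, and 0.05, 0.082 and 0.23 within replicate 1 and 0.11, 0.27 and 0.21 within replicate 2. Leaving out 1 SETD7 sample lowered it to 0.11 at day 2 without day 2 replicate 2 and 0.15 without day 0 replicate 1, to 0.084 at day 5 without day 5 replicate 2, and to 0.059 and 0.094 at day 9 without day 9 replicate 2 and day 5 replicate 1.

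H3K27ac was compared with day 0. At day 2 the highest list genes in the authors' deposited table were SP5 at a log2 fold change of 7.52, the streak homeobox gene EVX1 at 7.42, the WNT receptor-pathway gene LGR5 at 6.08, DKK1 at 6.06 and MIXL1 at 5.87. The lowest in the authors' deposited table were the pluripotency genes FOXD3 at -3.89, UTF1 at -3.21 and PRDM14 at -3.07, then TNNT2 at -2.79 and SOX2 at -2.62. Streak genes had a median of 4.15 at day 2, 0.56 at day 5 and -0.30 at day 9 in the authors' deposited table, at percentiles 100, 99.85 and 26.41 of random lists matched on RNA level. For pluripotency genes the authors' deposited table gave medians of -0.63, -3.02 and -4.34, at percentiles 0.04, 0 and 0, with NANOG at -0.57, -4.10 and -5.50. Cardiac progenitor genes had medians of 0.39, 3.0 and 3.50 in the authors' deposited table (percentiles 99.82, 100 and 100), with NKX2-5, the early cardiac homeobox gene, at -0.72, 1.46 and 5.56. Sarcomere genes had -0.22, 0.84 and 2.78 in the authors' deposited table (percentiles 3.98, 100 and 100), with MYH6 at 1.03, 2.63 and 6.44.

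WNT genes had H3K27ac medians of 2.16, 1.06 and 0.47 in the authors' deposited table, at percentiles 100, 100 and 93.5. Ion handling genes had -0.01, 0.57 and 1.10 in the authors' deposited table (percentiles 48.39, 99.86 and 100), and fibroblast and epicardium genes -0.06, 1.25 and 1.05 (34.56, 100 and 100). Cell cycle genes went from 0.09 to -0.24 and -1.40 in the authors' deposited table (percentiles 30.1, 1.9 and 0), and oxidative phosphorylation genes from 0.10 to 0.01 and 0.76 (58.18, 50.48 and 99.88). The authors' deposited table gave neural ectoderm medians of 0.22, -0.82 and -0.70, endoderm 0.21, -0.34 and -0.38, endothelium and blood 0.14, 0.21 and -0.19, and glycolysis -0.03, -0.35 and 0.02. Percentiles among random lists, computed here from the authors' deposited table, were 95.77, 0.04 and 4.12 for neural ectoderm, 94.93, 14.61 and 17.9 for endoderm, 91.55, 91.38 and 50.43 for endothelium and blood, and 4.87, 0.89 and 11.66 for glycolysis. The median was 0.27, 0.36 and 0.41 for methylation enzymes, 0.25, 0.05 and 0.24 for pausing and elongation, 0.42, 0.06 and -0.12 for ribosomal protein genes, 0.35, -0.20 and 0.19 for stress genes and 0.19, -0.15 and -0.39 for mitochondrially encoded genes in the authors' deposited table. Their percentiles, computed here from the authors' deposited table, were 91.28, 98.82 and 78.22, then 89.15, 48.29 and 43.78, then 98.59, 51.02 and 2.14, then 99, 18.43 and 64.69, and last 46.32, 13.83 and 1.79, in the same order. SETD7 itself stood at 2.24, 2.53 and 0.35 in the authors' deposited table. With 1 library per day these values have no replicate check.

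**Figure D3:**
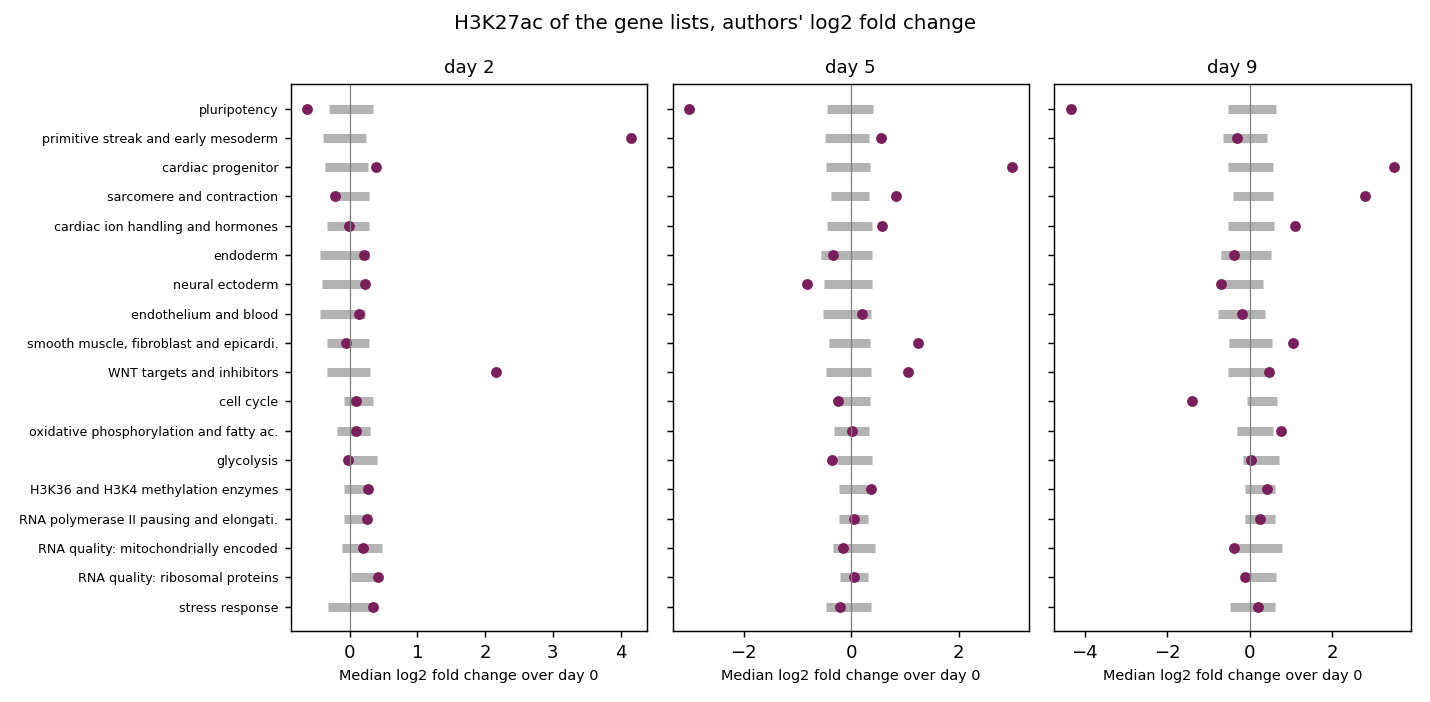
Median log2 fold change of H3K27ac over day 0 (x axis) for the 18 gene lists (y axis) at days 2, 5 and 9 in 3 panels, with a dot per list and a grey bar for the range of 95% of random lists matched on RNA level. Streak genes stood at 4.15 at day 2, and progenitor and sarcomere genes at 3.50 and 2.78 at day 9.

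Pol2 ChIP compared SETD7 mutant and wild-type HES3 mesoderm. Regions lower in the mutant outnumbered higher ones, at 1923 (70.9%) against 791 (29.1%) in the authors' deposited table, with median log2 fold changes of -0.61 and 0.63. The strongest loss in the authors' deposited table lay on chromosome 12 from 10059901 to 10064700, with counts of 65.14 and 40.07 in the mutant libraries and 906.23 in wild type (log2 fold change -4.11). Further losses in the authors' deposited table lay on chromosome 3 from 110687301 to 110689600 (-3.70), chromosome 6 from 118894701 to 118896400 (-2.92), chromosome 8 from 21902301 to 21904300 (-2.62) and chromosome 14 from 95230801 to 95232400 (-2.47). All 5 of the strongest gains in the authors' deposited table lay on chromosome X, from 117412901 to 117417000 (3.54), 118883301 to 118884800 (3.27), 118465801 to 118469600 (3.04), 117933401 to 117935300 (2.90) and 118340701 to 118344600 (2.85). At an absolute log2 fold change of at least 1 the authors' deposited table held 283 lower and 48 higher regions. Both mutant libraries lay on the same side of wild type in 1882 lower and 709 higher regions of the authors' deposited table.

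S2P, the elongating form, was lower in the mutant in 1175 regions (91.4%) and higher in 111 (8.63%) of the authors' deposited table, at median log2 fold changes of -0.98 and 0.31. Its strongest losses in the authors' deposited table lay on chromosome 12 from 10060901 to 10064300 (-3.79), chromosome 3 from 110687701 to 110689300 (-3.24), chromosome 6 from 166566001 to 166567200 (-2.80), chromosome 1 from 160655901 to 160658200 (-2.56) and chromosome 8 from 8918001 to 8919100 (-2.41). The strongest S2P gains in the authors' deposited table were on chromosome X, from 118342101 to 118343900 (3.41), 117415001 to 117416400 (2.98), 118466701 to 118467900 (2.76), 113282701 to 113289200 (1.12) and 113815701 to 113820700 (1.12). In the last 2 the gain lay mainly in 1 library, with mutant counts of 471.35 and 1112.36 against 365.19 in wild type, and 385.05 and 1197.99 against 364.25, in the authors' deposited table. At an absolute log2 fold change of at least 1 the authors' deposited table held 549 lower and 11 higher S2P regions. Both mutant libraries lay on the same side of wild type in 1170 lower and 97 higher S2P regions of the authors' deposited table. These counts compare the libraries and not the genotypes, and the spread between wild-type libraries is not in the tables.

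Of the 1175 S2P regions lower in the mutant in the authors' deposited table, 617 (52.5%) overlapped a lower Pol2 region. The median was 4 and the highest 14 after 100 shifts, which were not kept to Pol2-bound DNA and cannot show shared change. Of the 111 higher S2P regions in the authors' deposited table, 97 (87.4%) overlapped a higher Pol2 region, against at most 8 after shifting, and 4 higher and 5 lower S2P regions overlapped Pol2 regions of the opposite direction. Of 789 overlapping pairs from the authors' deposited tables, 780 (98.9%) had the same direction (Spearman correlation of log2 fold changes 0.87). The S2P change was larger in 637, which a p cutoff on reads can favour at low counts.

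H3K36me3 was called in 59719 peaks covering 89.3 Mb in the SETD7 knockout library and 56623 peaks covering 87.2 Mb in the wild-type library. Mean density in peaks was 15.6 and 18.0 normalized tags per kb, the share of tags in peaks was 13.96% and 15.66%, and median peak width was 727 and 760 bp. In the knockout 52.8% of peaks overlapped a wild-type peak (95% Wilson interval 52.4 to 53.2), and in the wild type 56.4% overlapped a knockout peak (56.0 to 56.8). Peaks in 1 library alone had a median width of 500 bp, against 1304 and 1242 bp for overlapping ones. The best-scored peak of either library lay on chromosome 6, from 3225995 to 3227727 in the knockout and 3226117 to 3227848 in the wild type. The next was on chromosome 20 in either library, from 47895213 to 47906715 and from 47895305 to 47907130. Then came chromosome 17 from 62223551 to 62224686, chromosome 11 from 94383458 to 94392066 and chromosome 12 from 131357267 to 131362284 in the knockout. In the wild type these were chromosome 7 from 83094620 to 83096361, chromosome 12 from 8077955 to 8087686 and chromosome 17 from 62223712 to 62224615, and all 10 peaks overlapped a peak of the other library. With 1 library per genotype, a different tag threshold and unequal depth, these shares have no replicate check.

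**Figure D4:**
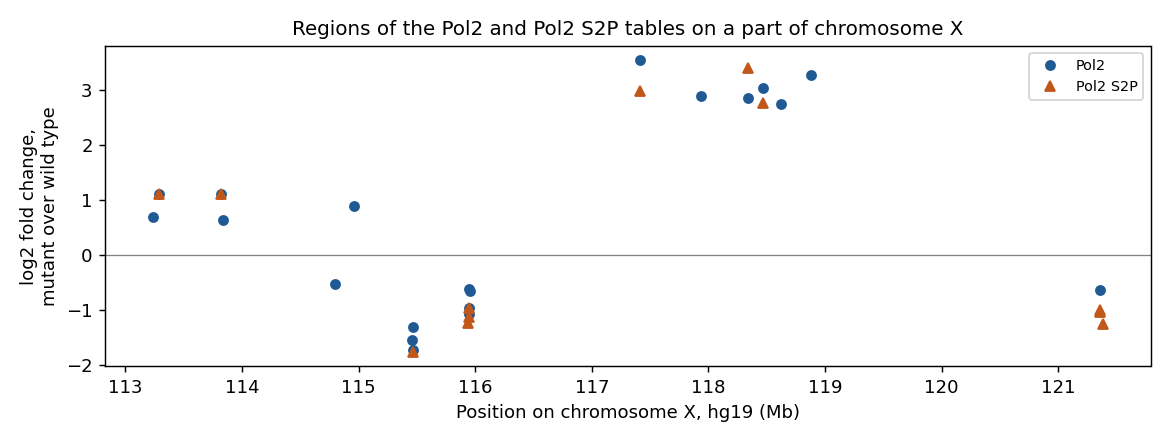
Log2 fold change of mutant over wild type in the authors' deposited tables (y axis) against position on chromosome X in Mb (x axis, hg19), with circles for Pol2 regions and triangles for S2P regions. From 117412901 to 118884800, 6 Pol2 regions lay between 2.75 and 3.54 and 3 S2P regions between 2.76 and 3.41.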

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

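Alternatives added after seeing the data were voom with and without the block, centring and left-out samples for the RNA lists, all SETD7 list tests, the SETD7 and RNA correlation with samples left out or quantile normalization, and the side on which each mutant library lay. Centring the RNA samples moved the lower calls at day 2 from 1809 to 3066, and fitting days 0 and 2 alone left 41 higher and 4 lower calls, where the fit had only 4 samples. At an adjusted p under 0.01 the RNA counts were 897 and 789 at day 2, 1033 and 899 at day 5, and 970 and 669 at day 9, a threshold that by construction keeps fewer genes. Other filters, scalings and voom kept all RNA counts within 1.5 times.

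With 1 sample left out, where the lone sample of a day is assumed to vary like the other days, RNA counts ran from 606 to 3804 higher and 481 to 3456 lower at day 2, 761 to 2913 and 653 to 2516 at day 5, and 605 to 2911 and 332 to 2627 at day 9. Higher lists ran from 18 to 19 and lower lists from 11 to 15. SETD7 counts without the block ran from 0 to 4 higher and 0 to 0 lower at day 2, 0 to 0 and 0 to 2 at day 5, and 0 to 1 and 0 to 0 at day 9. The SETD7 and RNA correlation ran from 0.11 to 0.24, 0.084 to 0.3 and 0.059 to 0.3 at the 3 steps, and with quantile normalization of the RNA it was 0.16 at day 2. Calling was not repeated with either mutant library alone. Among regions already listed from the mean, 1885 to 1920 lower and 727 to 773 higher Pol2 regions and 1170 to 1175 lower and 104 to 104 higher S2P regions lay on that side in a single library, which the selection favours. Omitting a day 0 RNA sample drops the widest replicate difference (SD over genes 1.26, others at most 0.79) from every step. Other causes were not tested.

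With the replicate block the SETD7 calls went from 0 to 28 higher and 40 lower at day 2 and to 7 and 2 at day 5, and voom with the block gave 33 and 54, and 11 and 6. The block changed no other SETD7 call beyond those given beside the results. RNA samples share only a number, since replicate differences correlated between days at -0.0012 to 0.12. The block moved their calls to 2116 and 1812 at day 2, 1819 and 1686 at day 5, and 1886 and 1479 at day 9, added a lower call for ribosomal protein genes at day 2 (adjusted p = 0.033) and ended the call of RPL7. No paired analysis was possible for H3K27ac, Pol2, S2P and H3K36me3 because the deposited values come from single libraries or the authors' own test.

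Of 94 named RNA values, 25 lost their call in at least 1 omission, 18 with only the compared days, 11 without the trend, 7 without the filter, 2 with quantile normalization and 1 with voom, and 0 changed direction. With an estimated correlation 5 higher and 5 lower RNA lists of 19 and 12 kept their call, and 0 of 28 SETD7 lists. Omissions ended 13 SETD7 list calls and added 28 in the same direction and turned the direction in 18 of 432. In RNA they turned it in 1, ribosomal protein genes at day 2, higher without day 0 replicate 1 (adjusted p = 0.00057; 5.2e-14 to 0.14 with another sample left out).

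The SETD7 ChIP lists turned to a call on the other side for cell cycle at day 2 (adjusted p = 0.0092 without day 0 replicate 2 and 0.0024 without day 2 replicate 1; 1.1e-08 to 0.05 where it stayed lower), ribosomal proteins at day 2 (0.0086 and 0.0089 without the same libraries; as low as 3.7e-13 without day 2 replicate 2) and at day 5 (0.00066 without day 2 replicate 2; 7.1e-12 to 0.98 where lower), glycolysis at day 5 (higher at 0.038 without day 2 replicate 2; 0.0069 to 0.35 with another left out), cardiac progenitor at day 9 (0.008 without day 5 replicate 1; as low as 1.2e-17 without day 5 replicate 2) and methylation enzymes at day 9 (lower at 0.028 without day 9 replicate 2; 0.035 to 0.86 with another left out). Called lists that turned and lost the call at day 2 were endothelium and blood (0.9 without day 0 replicate 2; as low as 0.0086), glycolysis (0.44; 2.8e-08), methylation enzymes (0.47; 0.0049 to 0.86 where lower), and pausing and elongation (0.16, and 0.61 without day 2 replicate 1; 0.00043). At day 5 this held for cell cycle without day 2 replicate 2 (0.13; 7.9e-12). At day 9 it held for sarcomere without day 5 replicate 1 (0.79; 7.4e-24), and without day 9 replicate 2 for cardiac progenitor (0.13), oxidative phosphorylation (0.33; 7.8e-07 to 0.86 where higher) and glycolysis (0.89; 1.7e-10). Their cause was not tested.

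Over the RNA filter alone, H3K27ac medians moved to 3.47 for streak and 0.45 for neural genes at day 2, -0.58 for neural genes at day 5 and -3.77 for pluripotency genes at day 9. At an absolute log2 fold change of at least 1, Pol2 kept 283 lower and 48 higher regions and S2P 549 and 11, and with overlap of at least 50% of the shorter region, opposite pairs fell to 1 and 3. Overlap of H3K36me3 peaks in knockout and wild type was 19.3% and 20.4% with at least 50% of each peak shared, 44.7% and 47.2% in the better-scored 50% of each list, 54.6% and 55.6% with equal numbers of peaks, and 51.9% in the knockout with peaks within 1 kb merged. The cause was not tested. Not run were SETD7 and H3K27ac within 1 kb of a start site, as no distance is given. Nor were Pol2, S2P and H3K36me3 at cardiac genes, without hg19 annotation. Depth limits the SETD7 table most in replicate 2, with as few as 5160872 reads.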

Other observations

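SETD7 signal with the block also changed at day 2 at genes outside the rule for named genes, chosen here after their values were seen. It rose at the Notch ligand gene DLL1 by 1.85 (SE 0.28, adjusted p = 0.019), at the segmentation clock gene HES7 by 1.68 (SE 0.31, adjusted p = 0.041), at the posterior homeobox gene CDX1 by 1.47 (SE 0.28, adjusted p = 0.046), at MSX1 by 1.33 (SE 0.23, adjusted p = 0.031) and at WLS, which carries WNT ligands to the surface, by 1.23 (SE 0.22, adjusted p = 0.036). It fell at the kinase gene PIM2 by 1.76 (SE 0.24, adjusted p = 0.011), the glucose transporter gene SLC2A3 by 1.84 (SE 0.22, adjusted p = 0.0086), the stem cell regulator gene TRIM71 by 1.34 (SE 0.21, adjusted p = 0.023) and the histone demethylase gene KDM6A by 1.10 (SE 0.18, adjusted p = 0.025). None of these was called without the block.

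Of S2P regions lower in the mutant in the authors' deposited table, 45.4% held a wild-type and 46.6% a knockout H3K36me3 peak, and of higher ones 9.01% and 14.4%. The values were 25.3% and 25.2% for lower and 7.84% and 8.47% for higher Pol2 regions in the authors' deposited table. Peaks were called apart in each library, so these shares do not measure a difference in H3K36me3.

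The patterns weighed below were picked after the results were seen. Their tests of day 9 RNA, a later-day label, a chance run, a low wild-type count, DNA copies and scaling were chosen only after the value was known, and those of length and whole-genome fragments before. In day 0 RNA, replicate 2 lay above replicate 1 at sarcomere genes by a median of 1.89, at progenitor genes by 1.53 and at fibroblast and epicardium genes by 1.27, with COL3A1 at 1.77 and 10.82, SMYD1 at 2.26 and 8.10, and TTN at 10.80 and 13.26. Mitochondrially encoded genes were also higher by 1.85 (13 of 13 genes), while ribosomal protein genes were lower by 1.93 (2 of 28 higher), stress genes by 1.32 and glycolysis by 1.04. RNA or cells of the day 9 samples would add the same share of the day 9 level to every gene, but over 45 genes that share differed 12.3-fold between its 10th and 90th percentiles (1.1 and 13.6 per 1000), which argues against it as the only source. A trend with gene length left the sarcomere median at 2.03, which argues against length. A later day labelled as day 0 would lower pluripotency genes, and their median difference was 0.15, which argues against it, although POU5F1 was 1.52 lower. The design gives no biological difference between these samples that could be tested, and a difference in RNA quality was not tested, so the source stays open.

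The 6 Pol2 regions on chromosome X with a log2 fold change of at least 2.5 in the authors' deposited table lay side by side between 117412901 and 118884800, and the size and the interval were set after this was seen. That size picks out only these regions and so tests nothing. At a size of at least 1, which 48 regions reached, the longest run was the same 6, and none of 10000 shuffles of fold changes gave more than 4. The share of 0.0001, the smallest they can give, argues against a chance run of independent regions, while neighbouring regions of 1 domain are not independent. The lowest S2P change in the interval was 2.76 in the authors' deposited table, which argues against a low wild-type Pol2 count alone, but wild type stood at the lowest count of either table, 14.07 in 1 Pol2 and 14.19 in all 3 S2P regions. H3K36me3 tags in the interval had a log2 ratio of knockout over wild type of -0.23 per covered kb and 0.1 in sum, but peaks called apart covered 48.4 and 38.4 kb, so more DNA copies in the mutant stay open. An effect of losing SETD7 and a difference between cell clones remain open and were not tested.

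SETD7 ChIP signal at the 13 mitochondrially encoded genes was higher at day 9 than at day 0 by a median of 2.28 (SD 0.24 over genes) in replicate 1 and 1.94 (SD 0.17) in replicate 2. Their share of reads went from 0.106% to 0.531% and from 0.0622% to 0.257%. No scaling factor changes this share, and its rise of 4.1-fold in the replicate with the smaller one argues against scaling of the day 9 libraries. Reads rose with gene length in every sample, with a lowest Spearman correlation of 0.73 and values of 0.9 and 0.95 at day 0, before the rise. Any source spread along the genes gives this, so fragments of the whole mitochondrial genome, more mitochondrial DNA per cell and binding by SETD7 cannot be told apart and stay open.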
